A study of Homo sapiens with 5 samples.

How the data were processed

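Gene expression was measured by RNA-seq in 5 libraries of the SAS line, 2 with control shRNA and 3 with shRNA against CCT2. Per the labels' protocols, RNA was extracted with Trizol, mRNA was selected with oligo(dT) beads and fragmented, and cDNA was made with random hexamers and sequenced on an MGI instrument. Per the labels, the raw reads of the set B libraries are no longer held, and reads were not used here. The authors deposited estimated counts per gene in 2 tables, set A (shCtrl 1, shCCT2 1 and 2) and set B (shCtrl 2 and shCCT2 3), named read counts per the file headers. Between 86.2% and 87.9% of the values in each library were whole numbers, so the deposited values are expected counts and not plain counts of reads.

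The submitters' processing notes name STAR 1.5.1, HTSeq and the mouse build mm10, without saying which file each applies to. The gene identifiers in the deposited tables carry a human taxon prefix, and 98.8% of the 15950 identifiers in set A and 98.7% of the 16219 in set B matched human genes of the RefSeq annotation of GRCh38.p14. The build and annotation behind the tables are therefore not given in the sources used here, no coordinates are printed, and GRCh38.p14 served only for names and for which genes neighbour each other. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart. Genes with near-identical relatives, such as the AKR1C, UGT1A and tubulin families, are uncertain. The symbols of 24 genes had been turned into dates and were restored from the gene identifier.

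The authors also deposited, for each library, a signal file of coverage along transcripts, with reads assigned to windows of relative position per the file headers. How it was made is not given in the sources used here, and it was read as position from one end of the transcript to the other.

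Groups and tables were taken from the labels. The tables were joined on the gene identifier, which 15187 genes share, and 763 genes listed in set A alone and 1032 in set B alone were not tested. Expected counts were rounded to whole numbers. The main test was edgeR 4.0.16's quasi-likelihood test in R 4.3.3 on all 5 libraries, with TMM scaling, edgeR's filter on low counts by group, and the table as a term beside the hairpin, so that each knockdown library is set against the control of its own table. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. The SE is the fitted log2 change divided by the square root of its F statistic. Log2 changes of single libraries come from TMM-scaled CPM with 0.5 added. The common biological coefficient of variation was 0.255. TMM factors were 0.965, 1.12, 0.935, 0.955 and 1.04 for shCtrl 1, shCtrl 2, shCCT2 1, shCCT2 2 and shCCT2 3. The median fitted log2 change of all genes was -0.016 with TMM, -0.013 with DESeq2's size factors and -0.081 without scaling.

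The design, the tests, the rule for named genes, 31 gene lists and most alternatives were fixed before the data were examined. The rule names CCT2, then the genes past the adjusted threshold with the same sign in all 3 knockdown libraries and a mean at or above the median of the tested genes, up to 12 per direction. Where fewer pass, it fills up to 6 per direction by the smallest unadjusted p, given as values that did not pass. It adds up to 4 members per list by the smallest p and any member of the CCT and PI3K-AKT lists. Lists with at least 5 tested members, 30 in all, were tested with camera in limma 3.58.1 at a preset gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. With an estimated correlation, camera uses the residual degrees of freedom of the fit, 2 in the main test and 1 in the interaction. On so few, a list can hardly pass. Members were also adjusted over the list alone. Values of some list members are not reported here.

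Libraries were checked for duplicates with a chi-square per degree of freedom, which was at least 20.3 for every pair, so no library was counted as a copy of another. Read position was tested with an exact permutation test. Runs of neighbouring genes were tested in windows of 50 genes with a mean of at least 5 CPM, on log2 CPM with 1 added, as the variance of the window medians over that of 1000 shuffled gene orders. Alternatives were no table term, the replicate number as a block, each library left out, set A alone, DESeq2 1.42.0, DESeq2's size factors, no filter and a stricter filter on low counts, robust estimation, other pseudocounts for the agreement of the tables, and the last 10% in place of the last 20% of windows for read position.

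The fit was tested on simulated counts with the real means, library sizes and spread, in which 200 genes were changed. Of those that passed the filter it called 0 of 194 genes changed 2-fold, 0 of 196 changed 4-fold and 138 of 193 changed 8-fold. It made 0, 0 and 8 false calls. In simulated lists, camera called the shifted list. Of the 9 unshifted lists, 0 were under 0.05. The simulated genes were drawn independently, so this check does not cover lists of correlated genes. In the real lists the estimated correlation reached 0.663, for G1/S and DNA replication genes. Totals of 16913600 to 18156600 counts put a counting error on CCT2 that is small beside the spread between libraries, with a counting interval (95%) of -1.35 to -1.25 for its log2 change in set B. Such intervals cover counting error only.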

Results

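The data are RNA-seq gene counts from SAS cells, an established human line of tongue squamous cell carcinoma. Cells carried control short hairpin RNA (shCtrl) or short hairpin RNA directed against CCT2 (shCCT2), which encodes a subunit of the cytosolic chaperonin CCT. CCT folds actin, tubulin and other proteins. There were 5 libraries in 2 separately deposited tables. One table, called set A here, held shCtrl 1, shCCT2 1 and shCCT2 2, and the other, called set B, held shCtrl 2 and shCCT2 3. The library totals were 17976500 counts in shCtrl 1, 16913600 in shCtrl 2, 18156600 in shCCT2 1, 17555800 in shCCT2 2 and 17715800 in shCCT2 3. The labels do not state whether the knockdown libraries carried 1 hairpin sequence or several, so agreement among them cannot exclude an effect of the hairpin on other genes. The labels do not state either that the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Each knockdown library was compared with the control of its own table, and log2 changes are knockdown minus control.

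The first question was whether the targeted gene was lower in the knockdown libraries. CCT2 (gene 10576) stood at 629.9 normalised CPM (counts scaled to library size) in shCtrl 1 and 642.4 in shCtrl 2. It stood at 296.1 CPM in shCCT2 1, 272.4 in shCCT2 2 and 260.2 in shCCT2 3. The log2 changes of the 3 knockdown libraries were -1.09, -1.21 and -1.30, in the direction the labels give, and the fitted change was -1.22 ± 0.18 (SE, 3 knockdown and 2 control libraries). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over all genes, CCT2 did not pass (adjusted p = 0.542). It passed with DESeq2's Wald test and the same adjustment (log2 change -1.21, adjusted p = 3.90e-05), and its adjusted p ran from 3.90e-05 to 0.99996 over the alternatives tried.

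The second question was which other genes moved with CCT2. The genes of this and the next paragraph were picked for the same sign in all 3 knockdown libraries, so that agreement is not a result. None passed edgeR's quasi-likelihood test over all genes (Benjamini-Hochberg adjusted p = 0.542 each), and they are given as values that did not pass. SPOCK1, which encodes the extracellular proteoglycan testican-1, was higher in all 3 knockdown libraries, with log2 changes of 1.91, 1.66 and 2.06 and a fitted change of 1.94 ± 0.22 (SE). FN1, which encodes the matrix protein fibronectin, was higher by 1.47, 1.57 and 3.06 on the log2 scale (fitted 2.15 ± 0.38), from 1884 CPM in shCtrl 1 and 493.2 CPM in shCtrl 2. SNAI2, a transcription factor of the Snail family, showed a fitted change of 1.01 ± 0.20. COL5A1, a fibrillar collagen gene, showed 1.05 ± 0.22. RASAL2, which encodes a Ras GTPase-activating protein, showed 1.02 ± 0.23, and MYBL1, a MYB-family transcription factor, showed 1.22 ± 0.31.

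Of the genes with lower values in the knockdown libraries, the tight-junction gene CLDN1 had log2 changes of -1.44, -0.99 and -1.24 in the 3 knockdown libraries (fitted -1.22 ± 0.21, SE). The desmosomal cadherin gene DSC3 had -1.64, -1.09 and -1.16 (fitted -1.28 ± 0.22). ALDH1A3, an enzyme of retinoic acid synthesis, had -1.60, -0.69 and -1.83 (fitted -1.41 ± 0.33), and the orphan receptor gene GPR176 had a fitted change of -0.90 ± 0.20. The ferroxidase gene CP was measurable in set B alone, where it stood at 213.8 CPM in shCtrl 2 and 4.64 CPM in shCCT2 3. In set A, CP had 3 counts in shCtrl 1, 0 in shCCT2 1 and 2 in shCCT2 2, so its fitted change of -5.24 ± 0.68 rests on the set B pair.

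Of 13123 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 lower at a Benjamini-Hochberg adjusted p under 0.05. The lowest adjusted p was 0.542. At an unadjusted p under 0.05 there were 372 higher and 600 lower genes, 972 in all, where 656 would be expected with no change. DESeq2's Wald test called 13 genes, 2 higher (SPOCK1, adjusted p = 7.80e-09, and FN1, adjusted p = 8.08e-06) and 11 lower. The 11 were CCT2, TNFSF10, CLDN1, UGT1A6, NUPR1, PADI3, DSC3, HES7, C15orf48, TMEM178B and ALDH1A3. NUPR1, C15orf48, PADI3 and TMEM178B had at most 14 counts in each set A library, so their values rest largely on the set B pair. Some of these were named because that count is small, after their values were seen. The fit had 2 residual degrees of freedom. In simulated data of the same design it called 0% of 2-fold changes, 0% of 4-fold changes and 71.5% of 8-fold changes.

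**Figure D1:**
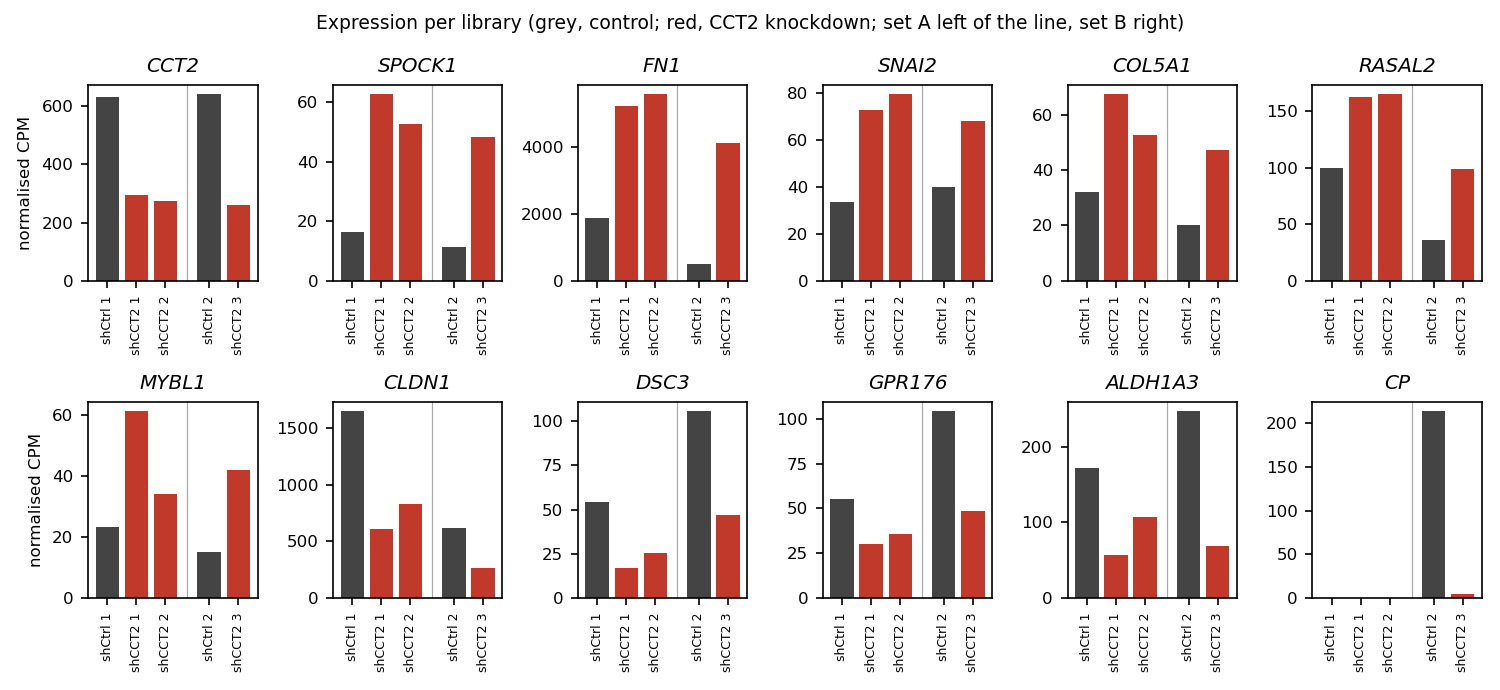
Normalised CPM (vertical axis of each panel, starting at 0) of CCT2 and 11 further genes in each library, 1 bar per library, grey for shCtrl and red for shCCT2, with the set A libraries left of the line and the set B libraries right of it. CCT2 stands at 629.9 and 642.4 CPM in the controls and between 260.2 and 296.1 CPM in the knockdown libraries.

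The title of the series links CCT2 to growth, migration and the PI3K-AKT pathway, so gene lists fixed before the data were examined were tested as groups. Genes of G1/S and DNA replication passed upward as a group in limma's camera test with a preset gene correlation of 0.01 (Benjamini-Hochberg adjusted p = 1.04e-11), but not with an estimated correlation (adjusted p = 0.741). The estimated version rests on the 2 residual degrees of freedom of the fit. A list can hardly pass on so few, so failing it does not decide, for this list or those below. Of 28 tested members, 26 had a higher fitted value, and the median log2 changes were 0.33 in shCCT2 1, 0.06 in shCCT2 2 and 1.46 in shCCT2 3. The fitted list median of 0.75 became 0.19 without shCtrl 2 or shCCT2 3, each of which leaves set A alone to give the change. It became 1.49 without shCtrl 1, which leaves the set B pair alone to give it. CCND1, which encodes cyclin D1, had a fitted change of 0.69 ± 0.19 (SE). RRM2, a subunit of ribonucleotide reductase, had 1.29 ± 0.36, with 0.86, 0.52 and 2.13 in shCCT2 1, 2 and 3. The transcription factor gene E2F2 had 0.88 ± 0.27, and CCNE2, which encodes cyclin E2, had 1.68 ± 0.55 with 0.83, 0.58 and 3.10. None of the members passed over all genes tested, and 0 passed adjusted over the list alone (edgeR, Benjamini-Hochberg).

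The mesenchymal and migration genes passed upward with camera's preset correlation (adjusted p = 0.00812) but not with an estimated one (adjusted p = 0.741), with 20 of 30 members higher and median log2 changes of 0.14, 0.13 and 0.43 in shCCT2 1, 2 and 3. FN1 and SNAI2 were the 2 members that passed adjusted over the list alone, and 0 passed over all genes (edgeR, Benjamini-Hochberg). TNC, which encodes the matrix protein tenascin-C, had a fitted change of 1.35 ± 0.38 (SE). Of the 30 members, 18 were higher in shCCT2 3, and 7 were higher and 3 lower in all 3 knockdown libraries. Among the members that went the other way in set B was the transcription factor gene ZEB1. It went from 63.6 CPM in shCtrl 2 to 7.53 CPM in shCCT2 3, and had at most 5 counts in each set A library. Without shCtrl 1 the list did not pass (adjusted p = 0.351), though its median was 0.54 there against 0.42 with all libraries. The median was 0.17 without shCtrl 2, 0.24 without shCCT2 1 and 0.15 without shCCT2 3.

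Type I interferon response genes passed upward with camera's preset correlation (adjusted p = 0.00159) but not with an estimated one (adjusted p = 0.741), with 19 of 25 members higher. Their median log2 changes were 0.62 in shCCT2 1 and 0.47 in shCCT2 2 but -0.04 in shCCT2 3. OAS3, an antiviral oligoadenylate synthetase, had a fitted change of 0.55 ± 0.19 (SE), the antiviral GTPase gene MX1 had 0.55 ± 0.23 and IFI6 had 0.67 ± 0.29. XAF1 had at most 2 counts in each set A library and stood at 5.89 CPM in shCtrl 2 and 20.8 CPM in shCCT2 3. None of the members passed over all genes, and 0 passed adjusted over the list alone (edgeR, Benjamini-Hochberg). The list median of 0.35 became -0.01 without shCtrl 1 (adjusted p = 0.886), 0.69 without shCtrl 2 and 0.65 without shCCT2 3.

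FOXO target genes passed downward with camera's preset correlation (adjusted p = 4.30e-05) but not with an estimated one (adjusted p = 0.741), with 15 of 20 members lower and median log2 changes of -0.46, -0.14 and -0.81 in shCCT2 1, 2 and 3. TNFSF10, which encodes the death ligand TRAIL, had -1.53, -1.58 and -2.08 (fitted -1.88 ± 0.29, SE) and was the 1 member that passed adjusted over the list alone. FOXO1 itself had a fitted change of -0.79 ± 0.23, the mitochondrial superoxide dismutase gene SOD2 had -0.86 ± 0.28 (-0.84, -0.27 and -1.29), and RBL2, a relative of the retinoblastoma gene, had -0.73 ± 0.24 (-0.62, -0.24 and -1.12). No member passed over all genes (edgeR, Benjamini-Hochberg). The list median of -0.54 became -0.84 without shCtrl 1 and -0.29 without shCtrl 2 or shCCT2 3.

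Targets of the oxidative stress regulator NRF2 passed downward with camera's preset correlation (adjusted p = 6.14e-05) but not with an estimated one (adjusted p = 0.743). The fitted value was lower for 18 of 22 members, but 15 of the 22 were higher in shCCT2 1, and 7 were lower in all 3 knockdown libraries. The medians were 0.07 in shCCT2 1, -0.52 in shCCT2 2 and -0.68 in shCCT2 3. The ferritin heavy chain gene FTH1 had -0.62, -0.67 and -1.12 (fitted -0.85 ± 0.21, SE), and PIR, which encodes pirin, had -0.67, -1.15 and -1.92 (fitted -1.42 ± 0.33). The aldo-keto reductase genes AKR1C2 and AKR1B10 were near 0 in set A. In set B, AKR1C2 stood at 783.5 CPM in shCtrl 2 and 15.8 CPM in shCCT2 3, and AKR1B10 stood at 18.9 and 0.655 CPM. AKR1C2 has near-identical relatives and had non-whole counts in 4 libraries, so its level is uncertain. Adjusted over the list alone 5 members passed, and over all genes 0 passed (edgeR, Benjamini-Hochberg). The list median of -0.41 became -0.66 without shCtrl 1, -0.68 without shCCT2 1, -0.19 without shCtrl 2 and -0.17 without shCCT2 3.

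Cholesterol synthesis genes passed downward with camera's preset correlation (adjusted p = 0.00159) but not with an estimated one (adjusted p = 0.741), with 18 of 23 members lower and medians of -0.34, -0.07 and -0.43 in shCCT2 1, 2 and 3. The enzyme genes HSD17B7, MVD and DHCR7 had fitted changes of -0.72 ± 0.25, -0.70 ± 0.25 and -0.57 ± 0.20 (SE), the last with -0.32, -0.38 and -0.85. None of the members passed over all genes, and 0 passed adjusted over the list alone (edgeR, Benjamini-Hochberg). Without shCtrl 1 the list did not pass (adjusted p = 0.0962), though its median was -0.41 there against -0.29 with all libraries.

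**Figure D2:**
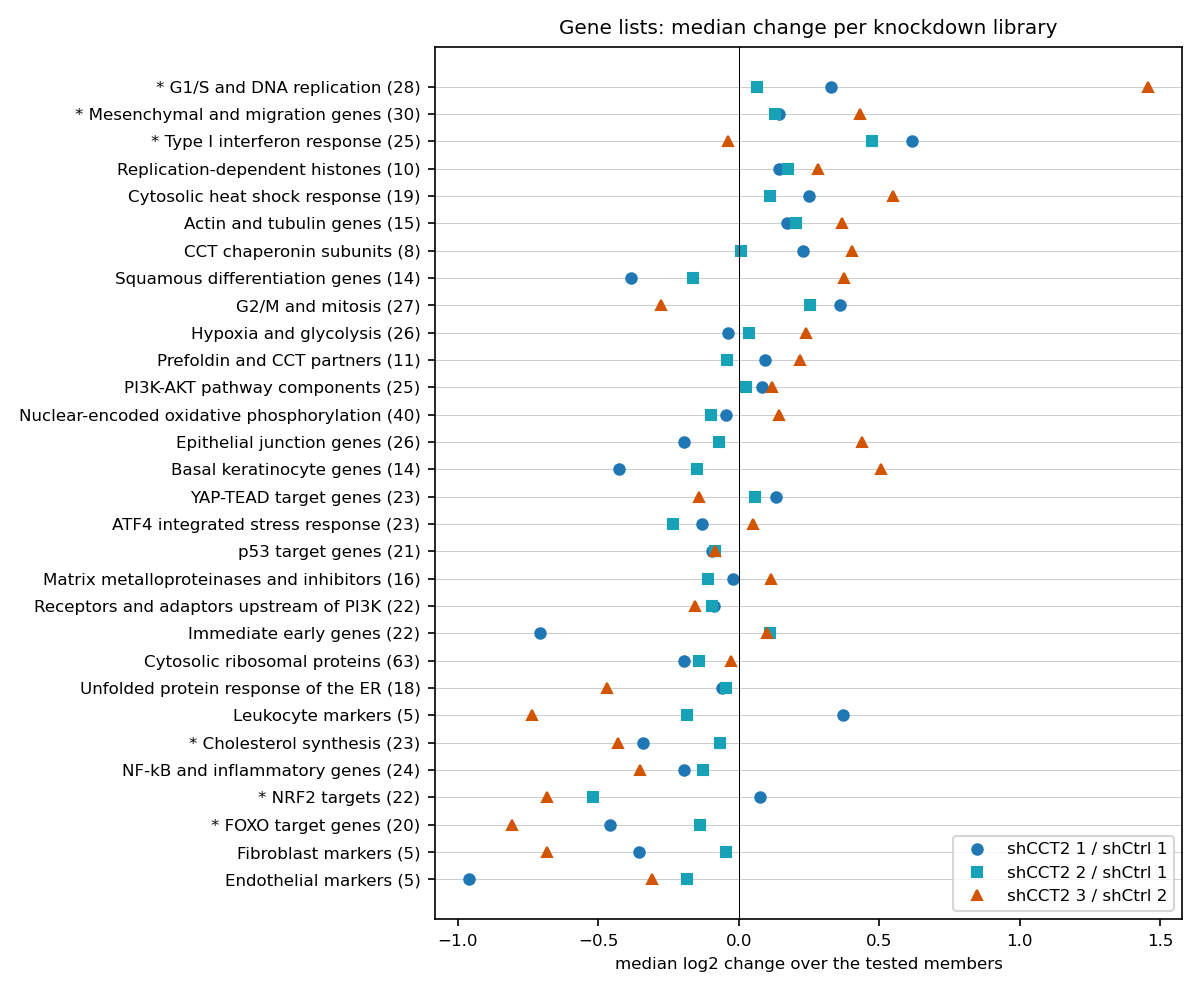
Median log2 change over the tested members (horizontal axis) of each of the 30 tested gene lists (number of members in parentheses), with 1 symbol per knockdown library against the control of its own table. Asterisks mark the 6 lists that passed camera with the preset correlation. G1/S and DNA replication genes stand at 0.33, 0.06 and 1.46, and FOXO target genes at -0.46, -0.14 and -0.81.

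Genes of the PI3K-AKT pathway did not pass as a group. Of 25 members, 17 had a higher and 8 a lower fitted value, the median log2 change was 0.04, and camera gave an adjusted p of 0.481 (0.767 with an estimated correlation). The median was 0.15 without shCtrl 1 and 0.08 without shCtrl 2 or shCCT2 3. AKT1 had a fitted change of 0.02 ± 0.18 (SE; 0.08, 0.07 and -0.06 in shCCT2 1, 2 and 3) and AKT2 had 0.32 ± 0.20 (0.09, 0.10 and 0.62). The kinase genes MTOR and PDPK1 had 0.61 ± 0.28 (0.36, -0.03 and 1.21) and 0.34 ± 0.18, and the AKT phosphatase gene PHLPP2 had 0.62 ± 0.24 (0.40, 0.35 and 0.91). The catalytic subunit genes PIK3CA and PIK3CD had -0.31 ± 0.18 and -0.48 ± 0.26, the latter with -0.57, -0.04 and -0.70. Receptors and adaptors upstream of PI3K did not pass either, with 17 of 22 members lower (camera, adjusted p = 0.302). GAB2, an adaptor gene, had a fitted change of -2.14 ± 0.75 (-0.80, -0.60 and -3.38), and the receptor gene FGFR3 had -0.88 ± 0.32 (-0.94, -0.26 and -1.23). EGFR had a fitted change of 0.69 ± 0.27 (0.67, 0.07 and 1.09) and the adaptor gene GAB1 had -0.56 ± 0.25. No member of either list passed, over all genes or adjusted over the list alone (edgeR, Benjamini-Hochberg). These are mRNA levels, and the phosphorylation that sets the activity of the pathway was not measured.

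CCT2 was the 1 member of its own complex that passed adjusted over the list alone, and no CCT subunit passed over all genes (edgeR, Benjamini-Hochberg). The fitted log2 changes of the other subunits were 0.67 ± 0.29 (SE) for CCT6A, 0.42 ± 0.23 for CCT3, 0.34 ± 0.21 for CCT7, 0.26 ± 0.20 for CCT5, 0.23 ± 0.19 for TCP1, 0.15 ± 0.19 for CCT4 and 0.07 ± 0.19 for CCT8. The values in shCCT2 1, 2 and 3 were 0.45, 0.04 and 1.25 for CCT6A, 0.34, -0.001 and 0.75 for CCT3, 0.26, 0.01 and 0.60 for CCT7, 0.12, 0.03 and 0.52 for CCT5, 0.18, -0.03 and 0.25 for CCT4, and 0.19, -0.02 and 0.03 for CCT8. The 8 subunits did not pass as a group (camera, adjusted p = 0.564), nor did prefoldin and other CCT partners (adjusted p = 0.564). The test of the subunits includes CCT2 itself, the 1 lower member against 7 higher ones, so it says little about a shared rise of the others. Actin and tubulin genes, whose products CCT folds, were higher in 11 of 15 cases, and did not pass (adjusted p = 0.0684). TUBA1B had 0.81 ± 0.27 (0.39, 0.39 and 1.41 in shCCT2 1, 2 and 3), TUBB4B had 0.61 ± 0.26 (0.17, 0.27 and 1.14) and TUBB6 had 0.61 ± 0.27 (0.17, 0.20 and 1.21). The tubulin genes are close in sequence, so reads can be shared among them. The cytosolic heat shock response did not pass (adjusted p = 0.201), with HSP90AA1 at 0.93 ± 0.35 (0.45, 0.21 and 1.79), HSPE1 at 0.60 ± 0.23 (0.37, 0.20 and 1.02), HSPA8 at 0.57 ± 0.24 (0.27, 0.22 and 1.03) and HSPA4L at -0.65 ± 0.27 (-0.38, -0.21 and -1.08).

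CLDN1 and DSC3, both lower, passed adjusted over the list of 26 epithelial junction genes alone, but the list did not pass (camera, adjusted p = 0.829), with median log2 changes of -0.20, -0.07 and 0.44 in shCCT2 1, 2 and 3. Basal keratinocyte genes (adjusted p = 0.829) held KRT17 at a fitted change of -1.08 ± 0.39 (SE; -0.83, -0.18 and -1.86 in shCCT2 1, 2 and 3) and COL17A1, a hemidesmosome collagen, at 0.90 ± 0.35 (0.33, 0.26 and 1.77), neither of which passed. SOX2, a stem cell transcription factor gene, was the 1 basal member that passed adjusted over the list alone (edgeR, Benjamini-Hochberg), at 21.1 CPM in shCtrl 2 and 2.68 CPM in shCCT2 3, with no more than 0.577 CPM in set A. Squamous differentiation genes did not pass (adjusted p = 0.829). Of the markers of other cell types, 5 fibroblast, 5 leukocyte and 5 endothelial genes were tested, and the lists did not pass (adjusted p = 0.972, 0.564 and 0.274). Within the fibroblast list, COL5A1 and ACTA2, which encodes smooth muscle actin, passed adjusted over the list alone in opposite directions (1.05 ± 0.22 and -1.14 ± 0.36).

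The remaining lists did not pass camera with the preset correlation either. The lowest adjusted p of these was 0.0631, for NF-kB and inflammatory genes, in which 18 of 24 members were lower, among them the chemokine genes CCL20 at -1.09 ± 0.32 (SE; -0.49, -0.72 and -1.68 in shCCT2 1, 2 and 3) and CXCL8 at -0.95 ± 0.32 (-0.45, -0.27 and -1.65). Cytosolic ribosomal protein genes were lower in 50 of 63 cases (adjusted p = 0.0684), with RPLP2 at -0.46 ± 0.18. Genes of the unfolded protein response were lower in 14 of 18 cases (adjusted p = 0.139), with MANF at -0.58 ± 0.21 (-0.40, -0.23 and -0.92). In G2/M and mitosis (adjusted p = 0.432), the proliferation marker gene MKI67 had 0.72 ± 0.26 and the kinetochore gene NDC80 had 0.51 ± 0.17. Among p53 targets (adjusted p = 0.562), the cell cycle inhibitor gene CDKN1A had 0.61 ± 0.19 and the stress cytokine gene GDF15 had -1.79 ± 0.48. The adjusted p was 0.302 for replication-dependent histones, 0.551 for hypoxia and glycolysis, 0.564 for YAP-TEAD targets and 0.795 each for ATF4 targets, of which NUPR1 alone passed adjusted over the list alone (fitted -3.02 ± 0.52, with 6, 0 and 1 counts in the set A libraries and 597 and 74 in set B), immediate early genes and nuclear-encoded oxidative phosphorylation. It was 0.983 for matrix metalloproteinases and their inhibitors. No mitochondrially encoded gene was among the tested genes.

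The third question was whether the knockdown gave the same changes in both tables. FN1, SPOCK1 and PHOSPHO2-KLHL23, a read-through transcript at 0.984 CPM, were the 3 genes at least 2-fold higher in all 3 knockdown libraries, and 14 genes, CCT2, DSC3 and TNFSF10 among them, were at least 2-fold lower. The read-through gene was named because the count is small, after its values were seen. Across the 13123 genes, the log2 changes of the tables correlated with a Pearson r of 0.300 and a Spearman rho of 0.344, and 62.3% had the same sign. The tables share no library, and genes are not independent replicates. With shCCT2 1 alone for set A, r was 0.360, and with shCCT2 2 alone it was 0.114. Of 54 genes at least 2-fold higher in set A and 1099 in set B, 11 were shared, where independent lists would share 4.52, but 13 of the 54 were at least 2-fold lower in set B, where 7.48 would be expected. Of 87 and 1817 genes at least 2-fold lower, 48 were shared, where independent lists would share 12.05, and 9 of the 87 were at least 2-fold higher in set B, where 7.29 would be expected.

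**Figure D3:**
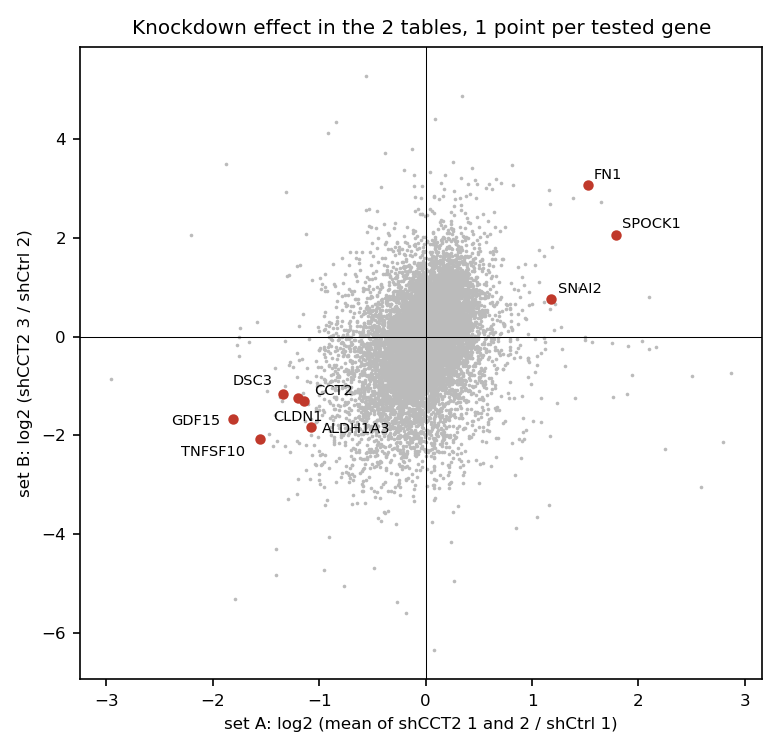
Log2 change of the knockdown in set A (mean of shCCT2 1 and 2 against shCtrl 1, horizontal axis) and in set B (shCCT2 3 against shCtrl 2, vertical axis), 1 point per tested gene, with 9 genes in red. Pearson r over the 13123 genes is 0.300, and CCT2 stands at -1.30 on the vertical axis.

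The difference between the tables was tested with an interaction term in edgeR's quasi-likelihood test, which left 1 residual degree of freedom. Its only replicates are shCCT2 1 and 2, since the control of each table and the knockdown of set B are single libraries. It called 0 genes after Benjamini-Hochberg adjustment (lowest adjusted p = 0.0932), with 2255 genes at an unadjusted p under 0.05 where 656 would be expected. DESeq2's Wald test of the same term called 263 genes, and edgeR called 185 with robust estimation and 15 with a stricter filter on low counts. For gene lists, camera with the preset correlation called 8 interaction terms. The shift of the G1/S and DNA replication genes was larger in set B (adjusted p = 1.08e-17), and that of the interferon genes was larger in set A (adjusted p = 0.000507). With an estimated correlation 0 lists passed (lowest adjusted p = 0.865). That version rests on the 1 residual degree of freedom, on which a list could hardly pass, so it does not decide on the 8 calls.

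The libraries of the tables also stood apart from each other in both groups. Log2 ratios over the tested genes had an SD of 0.451 for shCCT2 1 against shCtrl 1 and 0.293 for shCCT2 2 against shCtrl 1. The SD was 0.909 for shCCT2 3 against shCtrl 2 and 1.22 for shCtrl 2 against shCtrl 1, the control of one table against the control of the other. Pearson correlations of log2 CPM ran from 0.922 to 0.993 for the 4 pairs of libraries within a table and from 0.853 to 0.892 for the 6 pairs across tables. The secreted growth factor-like gene IGFL1 stood between 140.2 and 330.0 CPM in the set A libraries and at 0.0522 and 0.109 CPM in those of set B. SRGN, which encodes the proteoglycan serglycin, stood at 292.1 and 41.8 CPM in set B and at no more than 0.297 CPM in set A. IGFL1 and SRGN were singled out after their values were seen.

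**Figure D4:**
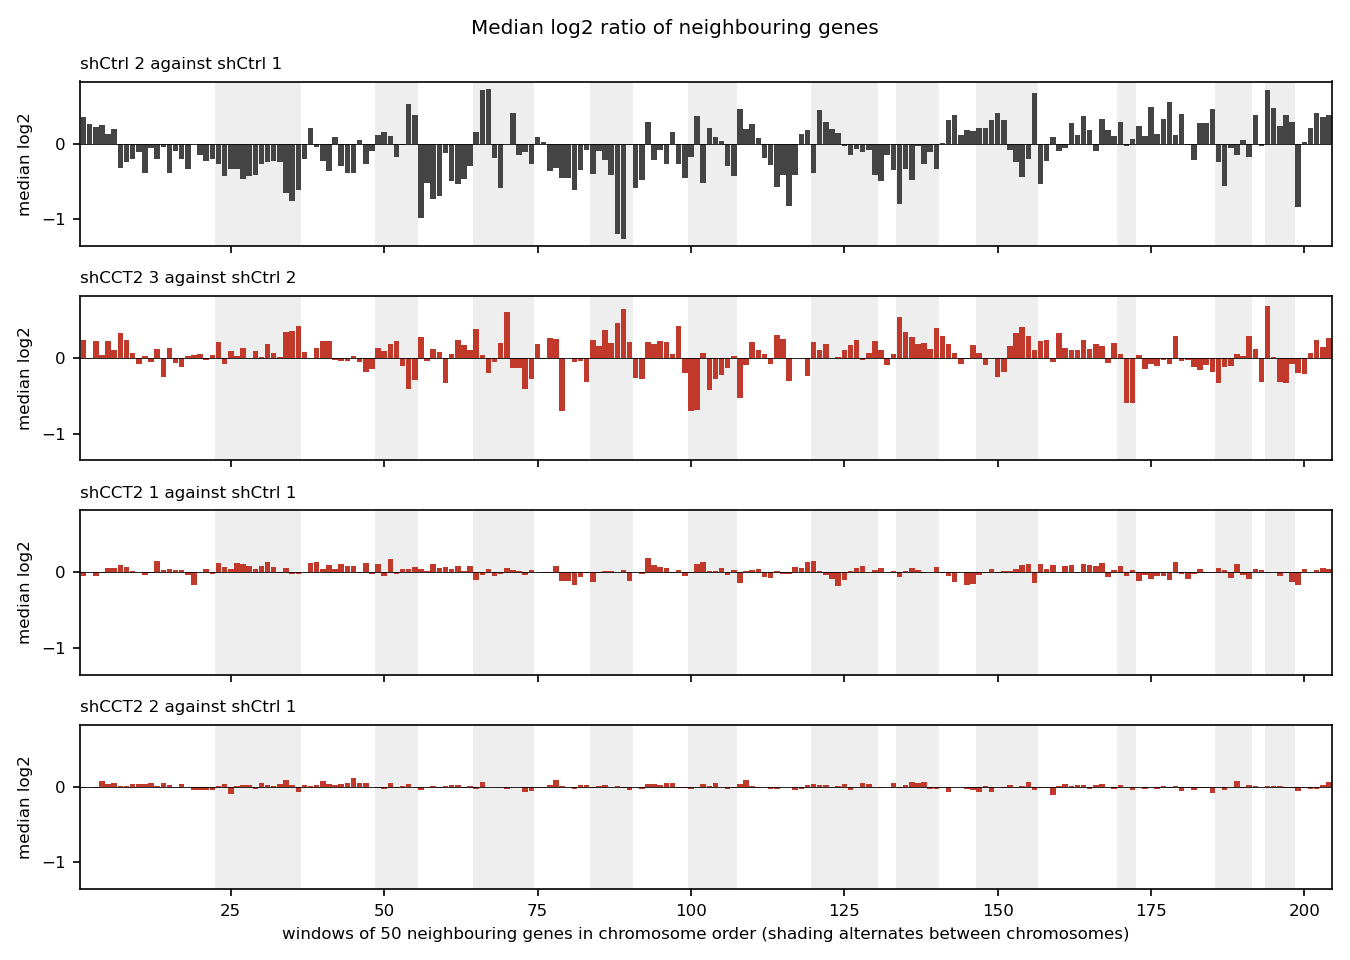
Median log2 ratio (vertical axis) in 204 windows of 50 neighbouring genes in chromosome order (horizontal axis, shading alternating between chromosomes), for shCtrl 2 against shCtrl 1 and for each knockdown library against its own control, 1 bar per window. The SD of the window medians is 0.352, 0.231, 0.0720 and 0.0352 from the top panel to the bottom panel.

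The position of reads along transcripts, a sign of RNA quality, was compared last. The last 20% of the windows held 16.7% of the position counts in shCtrl 1, 15.2% in shCtrl 2, 13.8% in shCCT2 1, 15.3% in shCCT2 2 and 14.1% in shCCT2 3. The means were 15.98% ± 1.04 (SD, n = 2) for shCtrl and 14.37% ± 0.79 (SD, n = 3) for shCCT2. The difference of -1.62 percentage points gave p = 0.3 in an exact two-sided permutation test, where 10 splits allow no p below 0.1. That test leaves out the table. Against the control of its own table, each knockdown library had a smaller share in the last 20% (by 2.94, 1.45 and 1.197 percentage points for shCCT2 1, 2 and 3) and a larger share in the first 20% (by 2.29, 0.699 and 0.870). The first 20% held 15.08% ± 0.79 (SD, n = 2) and 16.18% ± 0.85 (SD, n = 3), with p = 0.3 in the same exact test.

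**Figure D5:**
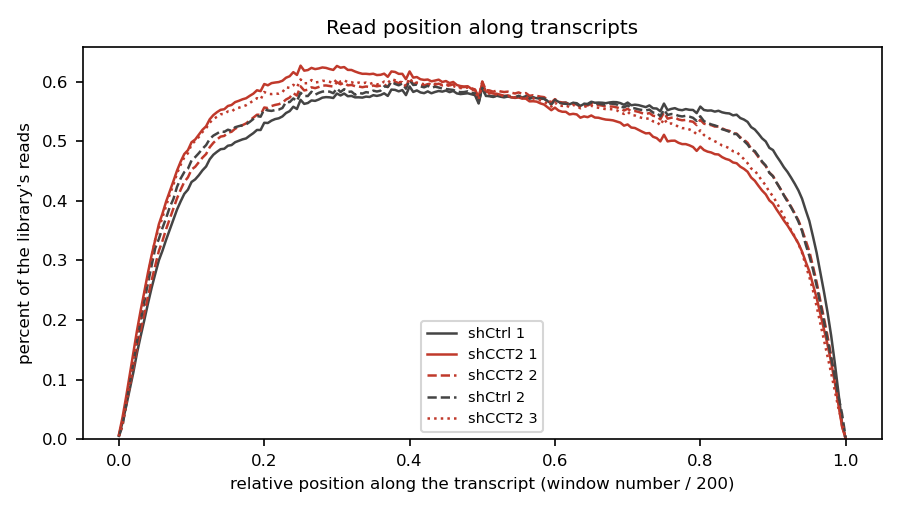
Percent of each library's position counts (vertical axis) in windows of relative position along the transcript (horizontal axis, 0 to 1), 1 line per library, dark for shCtrl and red for shCCT2. The last 20% of the windows holds between 13.8% and 16.7% of the counts, with shCtrl 1 highest.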

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

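The tests of sequencing depth, of read position and of a deeper loss of CCT2 were chosen only after the results were seen, and so was the reading of the set A test as open.

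For 8 gene lists the effect of the knockdown differed between the tables in a test of the interaction, whose only replicates are shCCT2 1 and 2 (limma's camera with the preset correlation, Benjamini-Hochberg adjusted), and 0 of them passed with an estimated correlation (lowest adjusted p = 0.865). The estimated version rests on 1 residual degree of freedom, on which a list could hardly pass, so it does not decide on these lists. With the preset correlation, the adjusted p was 1.08e-17 for G1/S and DNA replication genes, with medians of 0.33 and 0.06 in the set A libraries and 1.46 in shCCT2 3. It was 0.000275 for NRF2 targets, 0.000325 for G2/M and mitosis genes, 0.000507 for type I interferon genes and 0.00664 for epithelial junction genes. It was 0.00749 for basal keratinocyte genes, 0.0195 for squamous differentiation genes and 0.0391 for YAP-TEAD targets. G2/M genes had medians of 0.36 and 0.25 in set A and -0.28 in shCCT2 3, and basal keratinocyte genes had -0.43 and -0.15 in set A and 0.51 in shCCT2 3.

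The comparisons did not use the genes that 1 table alone lists, 763 in set A and 1032 in set B, of which 5 and 20 had 10 CPM or more in every library of their table. The highest were ITGA4, an integrin subunit gene, with a mean of 63.9 CPM in set A, and FAT1, which encodes a giant cadherin, with a mean of 299 CPM in set B.

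The libraries of the tables differed far more than knockdown and control libraries of set A. The set B pair came closer, with an SD of log2 ratios of 0.909 against 1.22 for shCtrl 2 against shCtrl 1. Both tables list 19 genes at 20 CPM or more in every library of one and at 1 CPM or less throughout the other. Genes that 1 table alone lists are not in this count. Of the 19, 15.8% had non-whole counts, against 19.1% of the other tested genes. The share was 0% of the 9 genes on in set A only and 30% of the 10 on in set B only. The pooled share argues against reads shared between genes, but less so for the genes of set B. The largest library total was 1.07 times the smallest, which argues against depth. For shCtrl 2 against shCtrl 1, the medians of windows of neighbouring genes varied 6.59 times as much as in shuffled gene orders (permutation p = 0.001, the smallest that 1000 shuffles give), against 1.82 and 1.47 times for the set A knockdown libraries (permutation p = 0.001 each). A candidate explanation is a different copy number of chromosome segments, as between sublines, clones or lines. The ratio met the outcome set beforehand for a different genome. It does not show which of these applies, and culture and library batch were not tested and stay open.

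The knockdown library of set B differed from its control more than those of set A from theirs. The share of reads in the last 20% of windows differed by 1.197 percentage points in set B and by 2.94 for shCCT2 1 in set A, which argues against read position. CCT2 was lower in set B than the mean of set A by a log2 difference of -0.15, which argues against a deeper loss of CCT2. Window medians varied 3.79 times as much as in shuffled gene orders (permutation p = 0.001, the smallest that 1000 shuffles give), and the set A libraries had the same p at 1.82 and 1.47 times, so the ratio and not the p sets set B apart. A different genome or a changed mix of cell populations between shCCT2 3 and shCtrl 2 may contribute, and with 1 library of each group in set B an effect of the knockdown itself stays open.

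The last pattern is the shift of 6 gene lists with the preset correlation. The calls would rest on the set B pair alone if few of them passed without it. Fitted on set A alone, 6 of the 6 passed in the same direction, the outcome set beforehand as speaking against that. It does not decide, since both knockdown libraries there share 1 control library and 15 of the 30 lists passed. Without shCtrl 1 the set B pair alone gives the change, so that fit does not decide either. With an estimated correlation 0 passed (lowest adjusted p = 0.741), but that version rests on the 2 residual degrees of freedom of the fit. A list could hardly pass on so few, so it does not decide either, and whether the lists moved stays open. The estimated correlation was 0.663 for G1/S and DNA replication genes but -0.023 for mesenchymal and migration genes. Correlation among genes therefore cannot account for the loss of every list, while the few residual degrees of freedom apply to all of them. For mesenchymal and migration genes camera's unadjusted p went from 0.0016 with the preset correlation to 0.070 with the estimated one.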

How the results depend on the processing

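Leaving out the genes over 2-fold apart between the tables was chosen only after the data were seen. The count of genes called (Benjamini-Hochberg adjusted) was 0 in edgeR without the table term, with the replicate block, in set A alone, with DESeq2's size factors, with either other filter, with robust estimation and among the 9765 genes left after 3345 genes apart between the tables were removed and the count filter was run again. It was 13 with DESeq2, and 0 to 2 with 1 library left out. The 2 came without shCCT2 2 and were CP (adjusted p = 0.0161) and CX3CL1 (adjusted p = 0.0338). CCT2 passed with DESeq2 (-1.21, adjusted p = 3.90e-05) and in no edgeR setting, and ran from -1.27 to -1.15 over all settings. The interaction called 15 genes with the stricter filter, 185 with robust estimation and 263 with DESeq2. The correlation of the tables was 0.360 with shCCT2 1 alone and 0.114 with shCCT2 2 alone.

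Lists called numbered 6 in the main setting, 10 with the replicate block, 15 in set A alone, 10 with the stricter filter, 3 to 16 with 1 library left out, and 0 with an estimated correlation or with fry. Of the main 6, 3 passed without the table term (adjusted p = 0.111 for mesenchymal, 0.558 for interferon and 0.784 for cholesterol synthesis genes), 3 without shCtrl 1 and 4 of them after genes apart between the tables were removed. The cause was not tested. With an estimated correlation the test rests on 2 residual degrees of freedom, on which a list can hardly pass.

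Deviations from the group means correlated at 0.68 for shCtrl 1 with shCCT2 1, at 0.60 for shCtrl 1 with shCCT2 2 and at 0.73 for shCtrl 2 with shCCT2 3. With 2 controls the deviations of one are the opposite of the other's, so shCtrl 2 with shCCT2 2 gives -0.60. The signs follow the table, and the check cannot tell whether the replicate numbers pair libraries. With the replicate block in place of the table term, which mixes the tables by construction, the log2 change turned to -0.38 for MX1, -1.37 for IFI6, -4.00 for XAF1, 0.90 for DHCR7, -0.025 for COL17A1, 0.23 for KRT17, 0.045 for CD68 and 0.061 for EGFL7. The list medians turned to -0.53 for interferon genes, -0.08 for mesenchymal genes (adjusted p = 0.453) and 0.48 for cholesterol synthesis (adjusted p = 0.0494). ZEB1 ran from -3.05 to 0.20 with 1 library left out, turning without shCtrl 2. Among list and gene values, 1145 kept direction and side of the threshold, 13 passed newly and 19 no longer passed.

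With 1 library left out, 47 of 87 followed genes moved by over 1.5 times, 46 of them without shCtrl 2, 40 without shCCT2 3 and 33 without shCtrl 1. Those settings take the change from set A alone or from the set B pair alone, so the counts reflect the contrast of the tables. The read position difference kept its sign, from -2.35 to -0.88 with 1 library left out and -0.78 in the last 10%. Quantile normalisation and pseudocounts in the gene test were not run, since the values are counts, and the interaction leaves no residual degree of freedom without shCCT2 1 or 2. Depth limits genes near 0 in one table, where changes rest on few counts.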

Other observations

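The genes named in this part were, apart from GDF15, chosen only after their values were seen. Several further genes were at least 2-fold lower in all 3 knockdown libraries. SERPINB3, a squamous serpin gene, had log2 changes of -3.48, -1.03 and -5.31 in shCCT2 1, 2 and 3, and GDF15 had -2.97, -1.17 and -1.67. UGT1A6, a glucuronosyltransferase gene, had -1.44, -1.38 and -4.30, and HES7, a Hes-family repressor gene, had -1.21, -1.20 and -3.19. The tight-junction gene CLDN16 had -1.82, -1.10 and -1.59 at a mean of 4.34 CPM. None passed edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.542 each), while DESeq2 called UGT1A6 (adjusted p = 9.88e-04) and HES7 (adjusted p = 0.0358). SERPINB3 and UGT1A6 have near-identical relatives, so their counts are uncertain.

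The change differed between the tables for 263 genes by DESeq2's interaction test (Benjamini-Hochberg adjusted), 94 of them opposite in sign, while edgeR's test of the same term called 0 genes (2255 at an unadjusted p under 0.05). The matricellular gene CTGF had log2 changes of 0.85 in set A and -3.87 in set B. SERPINB2, a plasminogen activator inhibitor gene, had -0.91 and 4.11. The growth factor gene HBEGF had -0.54 and 2.58. The control of each table and the knockdown of set B are single libraries, so these differences rest on the spread between shCCT2 1 and 2 alone.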
